A study of Homo sapiens with 14 samples.

How the data were processed

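PANC-1, an established human pancreatic cancer cell line, was treated for 12 h with gemcitabine, P276-00 or both, and the RNA was compared with that of vehicle-treated cells on 14 2-colour spotted oligonucleotide arrays, 1 per sample. Gemcitabine is a nucleoside analogue that interrupts DNA synthesis, and P276-00 is named in the series title as an inhibitor of CDK-4. The labels gave 5 treated groups: gemcitabine IC10 (2 arrays), gemcitabine IC50 (3), P276-00 IC10 (3), P276-00 IC50 (3) and the combination (3). IC10 and IC50 are the nominal doses for 10% and 50% inhibition. The labels state 100 nM for gemcitabine IC10 and 1000 nM for P276-00 IC50, which were also the doses of the combination (gemcitabine first, then P276-00). The concentrations of gemcitabine IC50 and P276-00 IC10 are not given in the sources used here. Total RNA was labelled by the indirect amino-allyl method, control RNA with Cy3 and treated RNA with Cy5 on every array, per the labels' protocols. One label field calls the control cells untreated and the treatment protocol calls them vehicle-treated; vehicle is used throughout, and which holds is not settled.

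Each array's table held, per the file headers, an intensity, the local background, a ratio and a signed fold change for each of 37632 spots (37631 on 4 arrays). The scanner, the image software and the authors' normalization are not given in the sources used here. The deposited intensity values plus the deposited background values reached exactly 65535, the scanner ceiling, in both channels, so the intensity values were taken as already background-subtracted. The deposited ratio was the quotient of the 2 intensities times 1 factor per array; it ran as Cy5 over Cy3 on 13 arrays and as Cy3 over Cy5 on P276-00 IC10 replicate 3 (r = -0.9999 with the log ratio of its intensities). The series matrix was the log2 of that deposited ratio, equal within 0.002 at 100% of the spots, so its scale, centring and direction are known. Its column medians were 0.138 and 0.0976 for gemcitabine IC10 replicates 1 and 2, 0.151, 0.0426 and 0.0841 for gemcitabine IC50 replicates 1 to 3, 0.164, 0.0426 and 0.0566 for P276-00 IC10, 0.164, 0.0976 and 0.0566 for P276-00 IC50, and 0.0426, 0.0144 and 0.0144 for the combination. It served as an alternative source of values, with the column of P276-00 IC10 replicate 3 turned.

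The design fixed before the data were examined called for a normexp background correction. This was not applied, because the intensities were already corrected. Spots that the files mark as bad were left out (0 to 1396 per array, the most on combination replicate 2). Each array has 48 print blocks of 28 rows and 28 columns. In 24 blocks on 5 arrays the intensities had been assigned to positions shifted by 1 to 3 columns. These blocks correlated with the same block on the other arrays at r of at most 0.169, against at least 0.711 for every other block, and at 0.900 to 0.964 once shifted back. Blocks under r = 0.5 were left out: 17 on P276-00 IC10 replicate 3, 3 on P276-00 IC50 replicate 2, 2 on gemcitabine IC10 replicate 2, and 1 each on P276-00 IC50 replicate 3 and combination replicate 1. In a test on simulated data, 10 of 10 moved blocks were found with the right shift and 0 others were called.

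Log2 ratios of Cy5 over Cy3 were normalized within each array by loess, with the 2537 control spots at weight 0, and spots of 1 probe were averaged. This gave 35035 probes, of which 35030 were tested, in R 4.3.3 with limma 3.58.1. All 14 arrays entered 1 fit with a coefficient per group, so that the groups shared an estimate of the spread (prior degrees of freedom 7.69 after empirical Bayes). Tests were two-sided, with Benjamini-Hochberg adjustment over all probes of a comparison and a threshold of 0.05. Of the 35030 probes, 1752 would be expected at an unadjusted p under 0.05 in each comparison by chance alone. The 11 comparisons were each group against vehicle, the combination minus each of its parts, the combination minus the sum of its parts, and the differences between doses and between the compounds. The dyes were never swapped. A probe's dye effect therefore adds to every comparison with vehicle, cancels in the differences between groups, and stays once, with its sign turned, in the combination minus the sum. The vehicle enters only as the Cy3 channel, so a ratio tested against 0 leaves out the spread between control cultures, and whether 1 control extract served all arrays is not stated. Nothing states that the replicates came from separate cultures, so the p-values measure the spread between these arrays, which may be technical.

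Probe annotation came from protein names in the array files. No protein name was given for 12402 probes, and those that passed are counted but not named. Symbols were assigned to 589 genes by matching the protein name, and other genes keep the name in the files. For each of 29478 genes the probe of highest mean intensity stood for the gene. Probes of 1 gene did not always move together: of the probes past the threshold that were not their gene's brightest, 6 under P276-00 IC50, 7 under gemcitabine IC50 and 12 in the combination minus the sum, the brightest probe had the same sign for 4, 7 and 10 genes and passed for 0, 2 and 1. The genes named by size had 8 other probes under P276-00 IC50, of which 4 had the same sign and 0 passed, 7 in the combination minus P276-00 IC50 (6 and 0) and 9 in the combination minus the sum (6 and 0). Gene lists fixed before the data were examined held 650 symbols, of which 624 were found. There were 22 lists: CDKs and cyclins; G1/S and DNA replication (E2F) genes; G2/M genes; p53 targets; DNA damage response and repair; pro-apoptotic genes; anti-apoptotic genes; immediate-early and short-lived transcripts; NF-kB targets; gemcitabine transport and nucleotide metabolism; the unfolded protein and integrated stress response. The others were heat shock proteins, interferon-stimulated genes, epithelial and mesenchymal genes, hypoxia and glycolysis genes, cholesterol synthesis, RNA polymerase II elongation and splicing, markers of other cell types, ribosomal proteins, oxidative phosphorylation, the proteasome and histones (core histones and the linker histones H1). The last 4 were fixed as patterns of gene symbols; since the files hold protein names, they were drawn with matching patterns of protein names, written once the files had been seen. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 22 lists of a comparison. The same test with a correlation estimated from the 27254 genes measured on every array, and fry, which asks whether a list's genes move on balance 1 way without comparing them with other genes, were run beside it.

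Genes were named by a rule fixed in advance. It took up to 10 of the largest rises and 10 of the largest falls past the threshold that went the same way on every array of the group (for differences, with no overlap between the groups' arrays). It added up to 4 genes per list with the smallest adjusted p, and always CDK4, CDK1, CDK9, CCND1, CDKN1A, MCL1, RRM1, RRM2, DCK and BIRC5. A probe was called above background where it exceeded the 95th percentile of the 424 negative-control spots in that channel. Where a gene's dimmer channel lay below this on every array of a group, only a lower bound of the fold is given, from means after loess and between-array quantile scaling of intensities; without dye swaps this bound is open to dye bias. A gene with a channel below this on every array of a compared group is left out of the ranges given for the always-named genes.

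The slide names fall into 3 series: series 15 (combination replicates 1 and 2), series 16 (8 arrays) and series 17 (gemcitabine IC10 replicate 1, gemcitabine IC50 replicate 3 and replicate 1 of each P276-00 dose). Series was treated as a batch: values are given with it as a block and within each series. Series 15 holds no group but the combination, so with the block the combination is compared with other groups through its replicate 3 alone. Against vehicle the block sets each group at the mean of the 3 series. The series 15 effect in that mean comes from the combination arrays alone. Blocked values of the single agents against vehicle are therefore no plain adjustment for batch. Alternatives fixed in advance were no background subtraction, median centring or print-tip loess in place of loess, added scaling of intensities, a filter on dim probes (9262 left out), the series matrix, series as a block, replicate number as a block, array weights, an intensity trend with robust variance, a fit of only the groups compared, leaving out each array, and, for the lists, the mean of all probes of a gene. Chosen after seeing the data were the fits without series 17 or with series 16 alone, shifted blocks kept as deposited or moved back, normexp with an offset of 50 on intensity plus background, and P276-00 IC10 replicate 3 or the combination arrays with their ratio turned. The planned settings were also run for the lists, a choice made at the same stage.

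The precision is limited by the number of arrays and by signal over background. On each array 39.2% to 61.2% of probes exceeded the 95th percentile of the negative controls in Cy5 and 34.4% to 61.6% in Cy3, and the median standard error of a log2 change was 0.205 for P276-00 IC50 against vehicle and 0.289 for the combination minus P276-00 IC50. Changes added to simulated data for P276-00 IC50 against vehicle (35030 probes) were recovered for 37% of probes at a log2 change of 1 and for 99% at 2, with 3 false calls. For the combination minus P276-00 IC50 these shares were 7% and 85%, with 4 false calls. A simulated shift of the histone list in gemcitabine IC50 against vehicle was recovered (camera adjusted p = 1.19e-30, 29478 genes), with 0 calls among the 21 other lists. The simulated noise was independent between probes and between arrays, with no correlation between genes and no profile shared by a slide series. The simulations therefore cannot tell how many false calls arise on the real arrays, where such correlation is present.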

Results

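Transcript levels were measured in PANC-1 pancreatic cancer cells 12 h after treatment with gemcitabine, P276-00 or both, each against vehicle-treated cells on the same array. The 14 arrays comprised 2 of gemcitabine IC10, 3 of gemcitabine IC50, 3 of P276-00 IC10, 3 of P276-00 IC50 and 3 of the combination of gemcitabine IC10 with P276-00 IC50. Median intensities ran from 752 to 1393 in Cy5 and from 649 to 1378 in Cy3, and after loess the log2 ratios of single arrays had an SD of 0.335 to 0.583. The number of arrays limits the precision. The series title names apoptosis and the sensitisation of these cells to gemcitabine as the subject, and the comparisons address what each compound did to transcript levels and what the combination added. In the combination gemcitabine was given first, so exposure times may differ from those of the single agents. Differences of the combination from its parts therefore cannot tell combined action from the schedule.

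The arrays also differed by slide series. The 4 arrays of series 17, each of another treatment, correlated with one another at r = 0.574 to 0.704 across probes (6 pairs, median 0.657), whereas arrays of the same treatment on different series had a median r of 0.0944 (9 pairs). Arrays of the same treatment on the same series ran from -0.0792 to 0.198 (4 pairs, median 0.171), so replicates correlated weakly within a series too. Within series 16 the correlations ran from -0.152 to 0.217 (28 pairs). All 3 combination arrays correlated negatively with the 4 arrays of series 17. Replicate 3 did so at -0.523 to -0.466, replicate 1 at -0.23 to -0.20 and replicate 2 at -0.21 to -0.16. The direction of combination replicate 3 was kept, because the labels state the dyes of both channels. The combination arrays correlated with each other at 0.198 to 0.408. Probes are not independent replicates, so these correlations describe the arrays only.

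**Figure D1:**
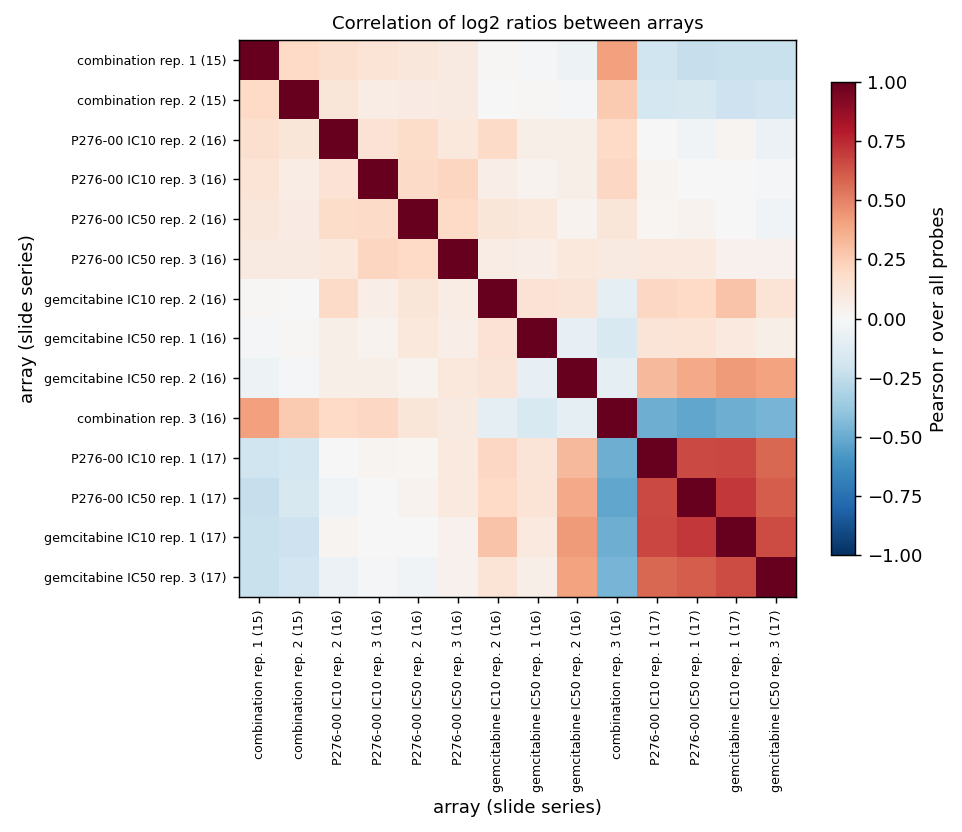
Heatmap of Pearson's r between the log2 ratios of each pair of the 14 arrays across probes, with arrays on both axes. The 4 arrays of slide series 17 form a block at 0.574 to 0.704. Combination replicate 3 stands against them at -0.523 to -0.466, and combination replicates 1 and 2 at -0.23 to -0.16.

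Gemcitabine IC50 lowered histone transcripts. Of 48 histone genes, which encode the core and linker proteins that package DNA, 16 fell when adjusted over all genes and 31 when adjusted over the list alone, and 44 had a negative log2 change (median -0.75, mean -0.79, n = 3). The largest falls were in Histone H2B.f (log2 -1.94, SE 0.20, limma adjusted p = 0.000433) and the linker histone H1.5 (-1.75, SE 0.177, adjusted p = 0.000366). Histone H2A 2-A fell by 1.71, H1.4 by 1.69 and H2B.r by 1.68 on the log2 scale. By class, 10 of 15 H2B genes fell (median -1.19), as did 4 of 19 H2A genes (median -0.64) and 2 of 7 H1 genes (median -0.83), but 0 of 5 H3 and 0 of 2 H4 genes passed limma's test (medians -0.32 and -0.45). Histone paralogs are near-identical, so which copies contributed is uncertain. GLE1, an mRNA export factor, rose on 3 of 3 arrays (log2 1.16, SE 0.190, adjusted p = 0.0202). CDKN1A, which encodes the CDK inhibitor p21, rose at least 1.40-fold on background-subtracted intensities (limma adjusted p = 0.0426), with only this bound because it was above background in Cy5 on 3 of 3 arrays and in Cy3 on 0 of 3. For gemcitabine IC50 against vehicle it was not called without background subtraction, where its log2 ratio of 0.35 lay under that bound (limma adjusted p = 0.134; 0.00659 to 0.826 over the alternatives). The remaining probe of the 3 that rose was 1 for UDP-glycosyltransferase 3 A1 (log2 1.25, adjusted p = 0.0155), which lies outside the naming rule and was chosen after its values were seen.

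In all, 30 of 35030 probes passed for gemcitabine IC50 against vehicle (3 higher, 27 lower), and 22 of the lower ones were histone probes. The histone list passed camera (adjusted p = 3.64e-42) and kept its call with an estimated correlation (adjusted p = 0.0348, 4.91e-46 to 0.0348 over the alternatives). With slide series as a block its median was -0.96, a value that takes in the series 15 effect of the combination arrays. Under median centring it was -1.03, and it was -0.67 within series 16 and -0.89 within series 17. Within these series H1.5 measured -1.61 and -2.03 and GLE1 1.18 and 1.12. With slide series as a block 2549 probes passed, without series 17 there were 14, and on series 16 alone 2. Leaving out replicate 1, 2 or 3 gave 19, 16 and 15 probes. The CDKN1A call ended without each of them (limma adjusted p = 0.162, 0.196 and 0.490; 0.00659 to 0.826 over the alternatives), and GLE1 went to 0.162, 0.0578 and 0.217 (0.00131 to 0.392). The H2A 2-A call ended too (0.0546, 0.0682 and 0.137), and that of H2B.r without replicate 2 (0.0503). Without background subtraction 10 of the 12 genes named here were smaller by over 1.5 times on the log2 scale, with 0 changes of sign. Among the 10 genes always named, the other 9 did not pass; the 7 measured above background ran from -0.02 for MCL1 to 0.49 for RRM1.

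Under P276-00 IC50 5 histone genes fell and a set of other single genes rose. Of the 48 histone genes, 25 fell when adjusted over the list alone and 42 had a negative change (median -0.55, mean -0.50, n = 3, camera adjusted p = 3.04e-24). The list's call was lost with an estimated correlation (adjusted p = 0.195, 1.34e-28 to 0.195 over the alternatives). H2B.f fell by 1.08 (SE 0.200, limma adjusted p = 0.049) and H1.5 by 1.07 (SE 0.177, adjusted p = 0.0295) on the log2 scale. HnRNP D0, an RNA-binding protein of AU-rich transcripts, fell by 1.05 (adjusted p = 0.0275). Among the rises were the corepressor TLE1 (log2 1.55, SE 0.232, adjusted p = 0.0237), DNA cross-link repair 1A (1.48, SE 0.214, adjusted p = 0.019), Collagen alpha-1(XIV) (1.46, SE 0.204, adjusted p = 0.0155), adenosylhomocysteinase 3 (1.42) and the actin regulator WASP-interacting protein (1.33). MDM2, the ubiquitin ligase that acts on p53, rose by 1.15 (SE 0.155, adjusted p = 0.0155). Other p53 targets did not pass, and the list's median was 0.07 (camera adjusted p = 0.0675). The ribosomal protein list lay higher by camera (median 0.14, 57 of 77 genes positive, adjusted p = 0.00324), but its median was -0.08 under median centring and 0.01 in the series matrix, and camera's direction turned in both. This call too was lost (adjusted p = 0.871 with an estimated correlation, 2.39e-06 to 0.871 over the alternatives).

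For P276-00 IC50 against vehicle, 43 probes passed (35 higher, 8 lower), of which 12 had no protein name. The ribosomal call also ended without replicate 1 (0.545). With slide series as a block the histone and ribosomal medians were -0.68 and 0.26, within series 16 they were -0.45 and 0.03, and within series 17 they were -0.67 and 0.26. The rises were larger on series 17 (TLE1 2.17, Collagen alpha-1(XIV) 1.73, WASP-interacting protein 1.68) than on series 16 (1.23, 1.33 and 1.16), whereas MDM2 measured 1.28 and 1.08. On the series 17 arrays of the other treatments TLE1 measured 1.41 for gemcitabine IC10, 1.24 for gemcitabine IC50 and 1.57 for P276-00 IC10. With series as a block 1194 probes passed, including all 43. In limma 0 passed without series 17 or on series 16 alone (2627 had an unadjusted p under 0.05 in the full fit), and 0 passed without replicate 1, 2 or 3. MDM2 then had adjusted p = 0.305, 0.114 and 0.188 (0.00241 to 0.347 over the alternatives). Without background subtraction 8 of 17 named genes were smaller by over 1.5 times on the log2 scale, and MDM2 ran from 0.58 to 1.36 over the alternatives. The always-named genes did not pass, and ran from -0.30 for RRM2, a ribonucleotide reductase subunit, to 0.34 for DCK, over the 6 above background.

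**Figure D2:**
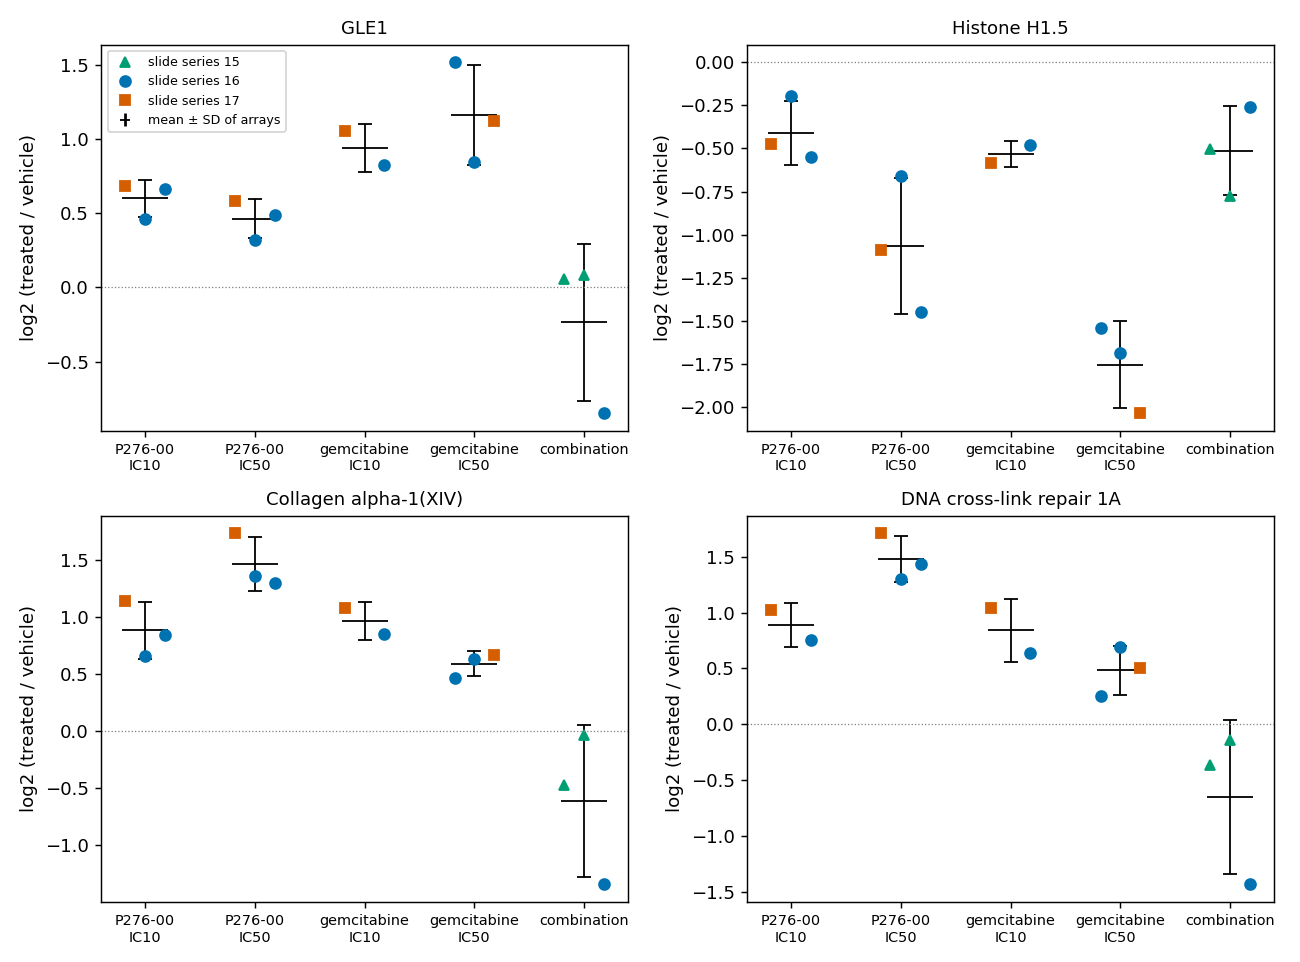
Log2 ratio of treated over vehicle on each array for GLE1, Histone H1.5, Collagen alpha-1(XIV) and DNA cross-link repair 1A, with points by slide series, the groups on the horizontal axis and bars for the mean and SD of a group's arrays. H1.5 averages -1.75 under gemcitabine IC50 and fell by 1.07 under P276-00 IC50, and Collagen alpha-1(XIV) averages 1.46 under P276-00 IC50.

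Between the 2 compounds at the same nominal inhibition, though not the same concentration, no single gene passed in limma (0 probes). An unadjusted p under 0.05 was reached by 1220 probes, fewer than the 1752 expected by chance. Both groups hold arrays of series 16 and 17 in the same proportion. The profile that the series 17 arrays share adds to the spread within groups but not to this difference. Its standard errors and limma p-values may therefore be too large. Of 48 histone genes, 42 had a higher log2 ratio under P276-00 IC50 than under gemcitabine IC50 (median difference 0.23, camera adjusted p = 2.79e-09), a call lost with an estimated correlation (adjusted p = 0.630, 1.88e-11 to 0.630 over the alternatives). CDKs and cyclins lay lower under P276-00 IC50 (median -0.12, 20 of 27 genes negative, adjusted p = 0.0361). That call was lost as well (adjusted p = 0.630 with an estimated correlation, 0.00483 to 0.630 over the alternatives). The always-named genes ran from -0.53 for RRM2 to 0.19 for MCL1, an anti-apoptotic protein. The histone difference was 0.23 with series as a block and 0.22 within each of series 16 and 17. That of the CDKs and cyclins was -0.12, -0.18 and -0.11, and its call ended without gemcitabine IC50 replicates 2 and 3 (0.200 and 0.287) or P276-00 IC50 replicates 2 and 3 (0.353 and 0.0703).

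At the lower dose of P276-00 no single gene passed in limma (0 probes, n = 3). An unadjusted p under 0.05 was reached by 1985 probes, against 1752 expected by chance, and 3 lists were called. None of the 3 held with an estimated correlation (adjusted p = 0.952 for each; 9.31e-11 to 0.952 for histones, 7.82e-13 to 0.997 for ribosomal proteins and 0.00254 to 0.997 for oxidative phosphorylation over the alternatives). Histone genes were lower by camera (median -0.22, 43 of 48 negative, adjusted p = 1.27e-05). Ribosomal protein genes were higher (median 0.17, 62 of 77 positive, adjusted p = 1.27e-05), with a median of -0.05 under median centring and -0.02 in the series matrix. Genes of oxidative phosphorylation were higher (median 0.14, 52 of 80 positive, adjusted p = 0.0147), with a median just under 0 under median centring. The deposited ratio of replicate 3 runs against its labelled dyes, and whether the dyes of that array were swapped is not settled. With its ratio turned the histone median was -0.07 (37 of 48 negative) and that of oxidative phosphorylation 0.11 (50 of 80 positive), and both calls ended (0.230 and 0.0557). The ribosomal list then had a median of 0.25 (70 of 77 positive) and kept its call (7.82e-13). Blocked by series the medians were -0.39, 0.24 and 0.16, within series 16 they were -0.17, 0.06 and 0.08, and within series 17 they were -0.36, 0.27 and 0.14. All 3 calls ended without replicate 1 (0.0777 each), 2 of them without replicate 2 (0.0992 ribosomal, 0.344 oxidative phosphorylation), and without replicate 1 there was 1 probe that passed. For P276-00 IC10 against vehicle 174 probes passed with series as a block. With replicate 3 in its labelled direction, which is not settled, the always-named genes ran from -0.33 for RRM2 to 0.30 for CCND1.

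Between the doses of P276-00, histone genes were lower at IC50 (median difference -0.32, 38 of 48 negative, camera adjusted p = 4.19e-11). The p53 targets were higher (median 0.11, 19 of 27 positive, adjusted p = 0.0319) and the hypoxia and glycolysis genes lower (median -0.19, 23 of 32 negative, adjusted p = 0.018). None of the 3 held with an estimated correlation (adjusted p = 0.416, 0.194 and 0.416; 6.61e-16 to 0.515, 0.00661 to 0.466 and 0.00340 to 0.515 over the alternatives). These differences too rest on P276-00 IC10 replicate 3, whose direction is not settled. With its ratio turned the medians were -0.42 (40 of 48 negative), 0.18 (19 of 27 positive) and -0.16 (23 of 32 negative), and the 3 lists kept their calls (6.61e-16, 0.0357 and 0.0177). With that replicate in its labelled direction, 0 probes passed in limma, and CCND1 differed by -0.31. An unadjusted p under 0.05 was reached by 895 probes, fewer than the 1752 expected by chance. The standard errors may again be too large, since both doses hold arrays of series 16 and 17 in the same proportion. Blocked by series the medians were -0.32, 0.11 and -0.16, within series 16 they were -0.28, 0.11 and -0.12, and within series 17 they were -0.31, 0.13 and -0.22. The p53 call ended with the block (0.0708) and without P276-00 IC10 replicates 1 and 2 (0.0958, 0.196) or IC50 replicates 2 and 3 (0.0590, 0.466). The hypoxia call ended without P276-00 IC10 replicate 2 (0.314) or IC50 replicates 1 and 3 (0.162, 0.0608).

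Under gemcitabine IC10, 67 of 77 ribosomal protein genes had a positive change (median 0.48, n = 2, camera adjusted p = 3.69e-15), a call lost with an estimated correlation (adjusted p = 0.358, 1.05e-18 to 0.358 over the alternatives). When adjusted over the list alone 26 rose and 1 fell, with 0 over all genes (4330 probes in limma had an unadjusted p under 0.05). The median was 0.17 under median centring and 0.28 in the series matrix, which moved the median of all probes by 0.130. Oxidative phosphorylation (median 0.22, 57 of 80 positive, adjusted p = 0.00129) and the proteasome (median 0.17, 28 of 39 positive, adjusted p = 0.00453) were also higher, with 4 and 5 genes passing when adjusted over the list alone. Both calls were lost with an estimated correlation (adjusted p = 0.358 for each; 0.000125 to 0.358 and 0.000276 to 0.358 over the alternatives). Histone genes were lower (median -0.14, 35 of 48 negative, adjusted p = 0.0398), with medians of -0.45 under median centring and -0.34 in the matrix. That call was lost too (adjusted p = 0.641 with an estimated correlation, 2.03e-07 to 0.641 over the alternatives). CDKN1A did not pass (limma adjusted p = 0.265) and was not above background in Cy3 on either array. The single probe that passed, for the mitochondrial DNA control region, rose on both arrays (log2 1.36, SE 0.185, adjusted p = 0.0476); it was chosen after its values were seen. In the order given the 4 list medians were 0.54, 0.25, 0.23 and -0.28 with series as a block, 0.33, 0.15, 0.12 and -0.12 within series 16, and 0.56, 0.23, 0.33 and -0.19 within series 17. Without replicate 1 the proteasome and histone calls ended (0.107 and 0.372) and 3 probes passed. For gemcitabine IC10 against vehicle 1789 probes passed with the block.

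Between the doses of gemcitabine, histone genes were lower at IC50 (median difference -0.56, 39 of 48 negative, 19 passing when adjusted over the list alone, camera adjusted p = 8.14e-29). Ribosomal protein genes were lower as well (median -0.44, 69 of 77 negative, adjusted p = 5.56e-18), as were oxidative phosphorylation (median -0.12, 56 of 80, adjusted p = 0.0041) and the proteasome (median -0.13, 27 of 39, adjusted p = 0.0368). None held with an estimated correlation (adjusted p = 0.0949, 0.313, 0.313 and 0.476; 1.46e-32 to 0.0949, 3.42e-31 to 0.313, 0.000533 to 0.473 and 0.000707 to 0.632 over the alternatives). In limma 0 probes passed, and 1 without gemcitabine IC10 replicate 2. An unadjusted p under 0.05 was reached by 954 probes, fewer than the 1752 expected by chance. Both doses hold arrays of series 16 and 17, so the standard errors of this difference may again be too large. Blocked by series the medians were -0.54, -0.38, -0.14 and -0.14, within series 16 they were -0.54, -0.33, -0.13 and -0.08, and within series 17 they were -0.70, -0.36, 0.01 and -0.17. Without gemcitabine IC10 replicate 1 the last 2 calls ended (0.473 and 0.596), and the proteasome call ended without gemcitabine IC50 replicate 1, 2 or 3 (0.0828, 0.125 and 0.0641).

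**Figure D3:**
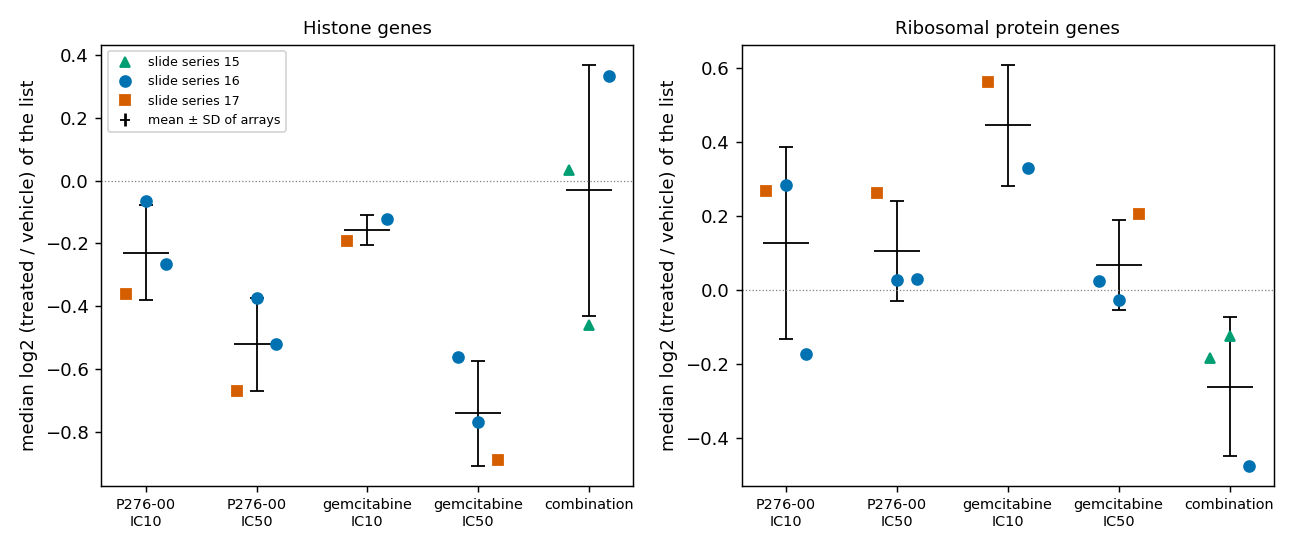
Median log2 ratio of treated over vehicle of the histone and ribosomal protein lists on each array, by group and slide series, with the mean and SD of each group. Histone medians lie at -0.56 to -0.89 under gemcitabine IC50 and spread from -0.46 to 0.33 under the combination. The drawn ribosomal means are 0.11 for P276-00 IC50 and 0.13 for P276-00 IC10. The medians over genes, which are not drawn, were 0.14 and 0.17, but -0.08 and -0.05 under median centring.

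For the combination no gene passed in limma (0 probes, 4849 at an unadjusted p under 0.05, smallest adjusted p = 0.198), and 2 lists were called by camera. Ribosomal protein genes had a median of -0.25 (61 of 77 negative, n = 3, camera adjusted p = 6.11e-07), and genes of the proteasome, which degrades tagged proteins, one of -0.21 (31 of 39 negative, adjusted p = 0.0133). Neither call held with an estimated correlation (adjusted p = 0.674 for both; 1.44e-10 to 0.674 and 0.000271 to 0.674 over the alternatives). Histone genes had a median of -0.05 and were not called, with array medians of 0.03, -0.46 and 0.33 (mean -0.03, SD 0.400). Under median centring their median was -0.19 and in the series matrix -0.20, and both called them lower (0.0111 and 0.00903; 0.000556 to 0.806 over the alternatives). CCND1, the cyclin partner of CDK4, measured 0.72 (adjusted p = 0.280) and DCK, the kinase that activates gemcitabine, -0.34. The medians were -0.31 and -0.26 with series as a block, -0.15 and -0.07 within series 15, and -0.47 and -0.35 within series 16, which holds replicate 3 alone. Without replicate 3 the proteasome call ended (0.132) and 1 probe passed, and with that replicate left out the histones were called lower as well (0.000556). For the combination against vehicle 1787 probes passed with series as a block, which sets the value at the mean of the 3 series and is no check of it. Median centring moved the median of all probes by 0.121 and the series matrix by 0.106.

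Compared with P276-00 IC50 alone, the combination had lower levels of 17 probes and higher ones of 0. The prion protein was lower by a log2 difference of -2.25 (SE 0.310, limma adjusted p = 0.0122), DNA cross-link repair 1A by -2.13 (SE 0.303, adjusted p = 0.0127), Collagen alpha-1(XIV) by -2.08 (SE 0.288, adjusted p = 0.0122) and WASP-interacting protein by -2.04 (SE 0.251, adjusted p = 0.0116). Shugoshin-like 2, a protector of centromeric cohesion, differed by -1.88. Of the 17 probes, 5 had no protein name. Histone genes were higher (median 0.55, 41 of 48 positive, 14 when adjusted over the list alone, camera adjusted p = 3.16e-09) and ribosomal protein genes lower (median -0.39, 60 of 77 negative, adjusted p = 1.22e-08). Neither list held with an estimated correlation (adjusted p = 0.468 for both; 2.27e-14 to 0.468 and 1.63e-09 to 0.468 over the alternatives). The P276-00 IC50 arrays enter both this comparison and that of P276-00 IC50 with vehicle, so a chance high value there shows in both.

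In the combination minus P276-00 IC50, the histone and ribosomal medians were 0.78 and -0.60 with series as a block, and 0.78 and -0.50 within series 16, where the prion protein differed by -2.60 and Collagen alpha-1(XIV) by -2.67. With the block 2510 probes passed, and on series 16 alone 148; in both the combination rests on replicate 3 alone, since series 15 holds no other group. In limma 0 passed without series 17 or without P276-00 IC50 replicate 1 or 2 (4595 had an unadjusted p under 0.05 in the full fit), 9 without its replicate 3, and 7 without combination replicate 3. Without background subtraction 3 of 10 named genes were smaller by over 1.5 times on the log2 scale, and with the combination's ratio turned 10 of 10, the prion protein then at -0.12. Median centring moved the median of all probes by 0.149. The always-named genes did not pass and ran from -0.68 for DCK to 0.73 for CCND1.

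Compared with gemcitabine IC10 alone, no gene of the combination passed over all probes in limma (0, with 6914 at an unadjusted p under 0.05), and 4 lists were called lower by camera. Of 77 ribosomal protein genes 69 had a negative difference (median -0.72, adjusted p = 2.01e-15), and 43 lower genes and 1 higher passed when adjusted over the list alone. Proteasome genes (median -0.49, 30 of 39 negative, adjusted p = 0.000646), oxidative phosphorylation (median -0.35, 58 of 80, adjusted p = 0.00271) and RNA polymerase II elongation and splicing (median -0.26, 37 of 48, adjusted p = 0.0367) were the others. None of the 4 calls held with an estimated correlation (adjusted p = 0.364 for the first 3 and 0.598 for RNA polymerase II; 1.92e-18 to 0.364, 2.35e-05 to 0.691, 0.000205 to 0.364 and 0.00159 to 0.691 over the alternatives). When adjusted over the list alone, 10 proteasome genes were lower and 1 higher, 5 genes of oxidative phosphorylation passed and 3 of RNA polymerase II. Large differences that did not pass were those of RPL23 (-1.59), RPS4X (-1.58), the glycolytic enzymes LDHA (-1.50) and ENO1 (-1.10), and the polymerase subunit POLR2A (-1.02). In the same order the list medians were -0.82, -0.53, -0.37 and -0.18 with series as a block, and -0.80, -0.47, -0.41 and -0.20 within series 16. The RNA polymerase II call ended with the block (0.165) and without gemcitabine IC10 replicate 1 or 2 (0.0755, 0.0814) or combination replicate 2 (0.0515). For the combination minus gemcitabine IC10, 2868 probes passed with the block, which leaves combination replicate 3 alone; without gemcitabine IC10 replicate 2 or combination replicate 3 it was 1. Median centring moved the median of all probes by 0.172, and the always-named genes ran from -0.92 for DCK to 0.40 for CCND1.

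Set against the sum of its parts, the combination departed from additive log2 changes at 98 probes (21 higher, 77 lower, 29 of them without a protein name). The fit treated the arrays as independent. P276-00 IC50 replicate 1 and gemcitabine IC10 replicate 1, both of series 17, correlated at r = 0.704, and their deviations from the group means at 0.551. The sum adds these 2 groups, so the standard errors and limma p-values of this comparison may be too small. Below the sum were the growth factor pleiotrophin (log2 -4.43, SE 0.861, limma adjusted p = 0.0480), thiamine transporter 1 (-4.39, SE 0.809, adjusted p = 0.0400) and Collagen alpha-1(XIV) (-3.04, SE 0.382, adjusted p = 0.00763). So were E2F2, a transcription factor of the G1/S transition (-2.37, SE 0.428, adjusted p = 0.0371), and MDM2 (-1.47, SE 0.291, adjusted p = 0.0486). Above it were Wnt-9a (2.43), a testis histone H2B (2.41) and ANKRD37, a hypoxia-inducible gene (2.28, SE 0.408, adjusted p = 0.0364). Ribosomal protein genes lay below the sum (median -0.87, 66 of 77 negative, 43 lower and 1 higher when adjusted over the list alone, camera adjusted p = 3.53e-14), as did oxidative phosphorylation (median -0.35, 59 of 80, adjusted p = 0.00201) and the proteasome (median -0.48, 28 of 39, adjusted p = 0.0131). None of these calls, nor that of the histones, held with an estimated correlation (adjusted p = 0.444 for each; 1.34e-16 to 0.444 for ribosomal, 0.000148 to 0.444 for oxidative phosphorylation, 0.00072 to 0.945 for the proteasome and 8.00e-13 to 0.444 for histones over the alternatives). The ribosomal median was -0.45 under median centring. The cytochrome c oxidase subunit VIIb, of oxidative phosphorylation, passed over all genes (-1.86, SE 0.337, adjusted p = 0.0373). When adjusted over the list alone, 8 genes of oxidative phosphorylation were lower and 2 higher, and 6 proteasome genes lower and 1 higher. Histone genes lay above the sum (median 0.76, 40 of 48 positive, 14 when adjusted over the list alone, adjusted p = 3.36e-07), a call lost likewise (adjusted p = 0.444 with an estimated correlation).

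A fixed dye effect does not cancel in the combination minus the sum of P276-00 IC50 and gemcitabine IC10. The ribosomal, oxidative phosphorylation, proteasome and histone medians were -1.11, -0.49, -0.52 and 1.08 with series as a block, and -0.83, -0.42, -0.41 and 0.91 within series 16, where Collagen alpha-1(XIV) measured -3.52. With the block 3722 probes passed and on series 16 alone 62, with combination replicate 3 alone in both. In limma 0 passed without series 17 or without gemcitabine IC10 replicate 1 (7586 had an unadjusted p under 0.05 in the full fit). Without gemcitabine IC10 replicate 2, 54 passed, without P276-00 IC50 replicates 1 to 3 in turn 6, 27 and 35, and without combination replicates 1 to 3 in turn 47, 62 and 14. Collagen alpha-1(XIV) lost its call without gemcitabine IC10 replicate 1 (0.0954; 0.000179 to 0.194 over the alternatives). MDM2 lost its call on leaving out any 1 array (limma adjusted p = 0.0601 to 0.335; 0.0136 to 0.549 over the alternatives), as did cytochrome c oxidase VIIb (at least 0.0504; 0.00267 to 0.622 over the alternatives). E2F2 ran from -3.33 to -0.19 over the alternatives (adjusted p = 0.000860 to 0.914). It measured -0.88 without background subtraction, where 17 of 23 named genes were smaller by over 1.5 times on the log2 scale, and -0.19 with the combination's ratio turned, where 11 were and 2 changed sign. Median centring moved the median of all probes by 0.123. The always-named genes did not pass and ran from -1.25 for DCK to 0.41 for CCND1.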

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

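The fits without series 17, on series 16 alone, with normexp on rebuilt foreground, with shifted blocks kept or moved back, and with turned ratios were chosen after seeing the data, as was running the planned settings for the lists. The counts of single genes depended on the processing, and the histone fall under gemcitabine IC50 kept its direction and call under every alternative run (adjusted p 4.91e-46 to 0.0348). The cause of each change below was not tested, except that fits with fewer arrays have less information. On each array 34.4% to 61.6% of probes exceeded the negative controls in Cy3. With dim probes left out, 57 of the 58 results of genes named by size kept their call.

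P276-00 IC50 against vehicle (43 probes) gave 5 without background subtraction, 0 under median centring, 0 in the series matrix, 1194 with slide series as a block, 0 without series 17, 0 on series 16 alone, 7 with normexp, and 0 to 0 when each array was left out. P276-00 IC10 against vehicle (0) gave 174 with the slide block, 31 in a fit of its own arrays, and 0 to 1 on leaving out arrays. The comparison of gemcitabine IC50 against vehicle (30, 3 higher and 27 lower) gave 2549 with the slide block, 14 without series 17, 2 on series 16, 18 with normexp, 14 from its own arrays, and 15 to 19 on leaving out arrays. It gave 23 (0 higher, 23 lower) both under median centring and in the matrix. That of gemcitabine IC10 against vehicle (1) gave 0 under median centring, 0 in the matrix, 1789 with the slide block, 0 with array weights, 3 without series 17, 0 on series 16, 0 with normexp, 313 from its own arrays, and 1 to 3 on leaving out arrays. The combination against vehicle (0) gave 8 without background subtraction, 11 under median centring, 6 in the matrix, 1787 with the slide block, 361 with array weights, 27 without series 17, 1763 on series 16, and 0 to 1 on leaving out arrays.

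The combination minus P276-00 IC50 (17) gave 4 without background subtraction, 0 under median centring, 7 in the matrix, 2510 with the slide block, 28 with array weights, 0 without series 17, 148 on series 16, 0 with normexp, 1 with the combination's ratio turned, 0 from its own arrays, and 0 to 25 on leaving out arrays. The combination minus gemcitabine IC10 (0) gave 3 without background subtraction, 2868 with the slide block, 1 without series 17, 19 on series 16, and 0 to 1 on leaving out arrays. P276-00 IC50 minus P276-00 IC10 gave 0 throughout. Gemcitabine IC50 minus IC10 gave 0 to 1 on leaving out arrays, and P276-00 IC50 minus gemcitabine IC50 gave 1 with the slide block. The combination minus the sum of P276-00 IC50 and gemcitabine IC10 (98) gave 19 without background subtraction, 0 under median centring, 65 with print-tip loess, 0 in the matrix, 3722 with the slide block, 0 without series 17, 62 on series 16, 0 with normexp, 9 with the ratio turned, 33 from its own arrays, and 0 to 62 on leaving out arrays. With slide series as a block, values against vehicle depend on how the block is coded. Here each group is set at the mean of the 3 series, and the series 15 effect comes from the combination arrays alone. Blocked values, counts and calls of the single agents against vehicle are therefore no plain adjustment for batch. Differences of the combination from other groups rest on its replicate 3 alone, since series 15 holds only the other 2 combination arrays. These blocked values are no check of the combination's results.

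The gene lists gave 31 calls in 242 tests (10 higher, 21 lower). With an estimated correlation 1 remained and fry gave 15. Median centring gave 35 (6 higher, 29 lower) and the matrix 33 (6 higher, 27 lower), and leaving out arrays 27 to 33. Some directions reversed. The ribosomal list for P276-00 IC50 reversed under median centring (adjusted p = 0.532) and in the matrix (0.714; 2.39e-06 to 0.871 over the alternatives), and for P276-00 IC10 likewise (0.969 and 0.997; 7.82e-13 to 0.997). With the combination's ratio turned, its ribosomal list (6.11e-07; 1.44e-10 to 0.674) and proteasome list (0.0133; 0.000271 to 0.674) reversed by construction, and so did the ribosomal list of the combination minus P276-00 IC50 (0.137; 1.63e-09 to 0.468), AP-3 beta-2 (-0.51) and thiamine transporter 1 (0.41) in the departure from the sum. The uncalled histone list of the combination changed direction with the slide block (0.806), on series 16 (0.0771), with the ratio turned (0.578) and without combination replicate 2 (0.182; 0.000556 to 0.466 on leaving out arrays and 0.000556 to 0.806 over all alternatives), and was called lower without its replicate 3 (0.000556), under median centring (0.0111) and in the matrix (0.00903).

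Of the 58 results of genes named by size, 58 kept their call with slide series as a block, those of the combination from replicate 3 alone, 50 with print-tip loess, 15 in the matrix, 14 without background subtraction, 11 with normexp and 10 under median centring. Of the 56 that could be fitted without series 17, 9 kept their call, and on series 16 alone 16 of 56. Whether the replicate numbers pair the arrays is not settled. Of 26 same-numbered pairs, 13 had deviations correlated above 0.1 (-0.388 to 0.563, against -0.559 to 0.451 for 52 other pairs), and 8 of 14 arrays correlated best with their own number. Between the P276-00 doses the same-numbered pairs correlated at 0.563, 0.329 and 0.2535. Replicate 1 of gemcitabine IC10 and of each P276-00 dose lies on series 17, so number and series partly coincide. With replicate number as a block, gemcitabine IC10 gave 0 probes, gemcitabine IC50 24, the combination minus the sum 56 and the lists 28 calls, and 40 of these 58 results kept their call.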

Other observations

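The tests of slide series and of dye for the histone list, of the wider set of histone variants, of slide series for the shared profile and for the departure from the sum, and the counts of splits were chosen after the results were seen. Lists of apoptosis, the cell cycle phases, DNA repair and gemcitabine handling had no camera call in any of the 11 comparisons. Pro-apoptotic genes had medians between -0.09 and 0.17 (smallest camera adjusted p = 0.350) and anti-apoptotic genes between -0.06 and 0.18 (0.0710). G1/S and DNA replication genes lay between -0.13 and 0.12 (0.0972), G2/M genes between -0.12 and 0.05 (0.389) and DNA damage response and repair genes between -0.07 and 0.00 (0.578). Gemcitabine transport and nucleotide metabolism lay between -0.26 and 0.09 (0.268).

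No camera call was given either to these stress, signalling and marker lists. Immediate-early and short-lived transcripts had medians between -0.25 and 0.05 (smallest camera adjusted p = 0.154). In the combination minus the sum fry called them lower (median -0.25, 33 of 51 negative, fry adjusted p = 0.0470). Fry gave 6 list calls in that comparison, the p53 targets among them (median -0.30), a list that camera called only between the doses of P276-00. NF-kB targets had medians between -0.12 and 0.13 (0.414), the unfolded protein and integrated stress response between -0.31 and 0.21 (0.151), heat shock proteins between -0.09 and 0.12 (0.422) and interferon-stimulated genes between -0.13 and 0.08 (0.334). Epithelial and mesenchymal genes lay between -0.07 and 0.15 (0.218), cholesterol synthesis between -0.19 and 0.14 (0.270) and markers of other cell types between -0.13 and 0.06 (0.334). A list without a call is not shown to be unchanged.

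Histone transcripts were lower under gemcitabine IC50; the difference from gemcitabine IC10, in which a fixed dye effect cancels, was -0.56, and it was -0.54 inside series 16 and -0.70 inside series 17, which argues against dye and against slide series as the whole source. Among 10000 random lists of like brightness 0 had a median as low (lowest -0.22). These lists drew other genes at random, whereas near-identical histone paralogs may move together. Their medians may therefore spread less than those of lists with such paralogs. A candidate explanation is a fall of replication-dependent histone transcripts when DNA synthesis stops: 8 genes named in advance as replacement variants had a median of -0.25 and the other 40 one of -0.84, a difference of -0.59 (exact permutation test, one-sided p = 0.00477). With H2A-Bbd and H2A.J, variants left among the 40, moved to the 8, the difference was -0.60 (exact permutation test, one-sided p = 0.00133). Under gemcitabine IC10 the order was reversed, with medians of -0.28 for the 8 variants and -0.14 for the 40 others. These medians were -0.39 and -0.61 under P276-00 IC50, -0.14 and -0.23 under P276-00 IC10, and 0.14 and -0.07 under the combination. The permutation tests treated the histone genes as independent. Near-identical paralogs need not be, so the p-values of these tests may be too small. The tests also took no account of histone class, and all 15 H2B genes (median -1.19 under gemcitabine IC50) were among the 40. They therefore cannot tell replication dependence from histone class. The candidate explanation remains a hypothesis, since DNA synthesis was not measured and paralogs were not resolved.

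The 4 arrays of slide series 17 shared a ratio profile across 4 treatments. Their median r was 0.657. This is how the pattern was found, so it tests no effect of the slide series, and arrays of different treatments inside series 16 had a median r of 0.102. Print-tip loess left it at 0.656, which argues against smooth spatial trends. What differed between the series in the laboratory is not recorded in the labels, an effect of series 17 stays open, and no biological explanation was tested.

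The departure from the sum held 98 probes. Without the series 17 arrays 0 passed, while the median size went from 2.42 to 1.94 and 95 of 95 measured probes kept their sign, so slide series stays open for the calls, with fewer arrays in that fit. A dye effect that stays in this contrast would show on arrays the contrast does not use. There the signed median was 0.449 (0.361 to 0.524 on the 4 single arrays), in the direction of a dye effect. These arrays carry the same 2 compounds at other doses, so a response shared between doses could give the same sign and is not told apart from dye. P276-00 IC10 replicate 3, whose direction is not settled, is among them. The median departure of 2.42 is larger, which argues against dye as the whole source. That size is inflated, since the 98 probes were chosen in this same contrast, and dye as a part of it stays open. An interaction of the compounds and the schedule in which they were given stay among the open explanations, as untested.

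The 10 splits of 6 arrays into 3 and 3 cannot give a share under 0.1. For the combination minus P276-00 IC50 the real split gave 17 probes and the highest other 1, so that 1 of 10 splits gave as many. For P276-00 IC50 minus P276-00 IC10 and for P276-00 IC50 minus gemcitabine IC50 the real split gave 0, the highest other 0, and 10 of 10 splits as many.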
